A study of Danio rerio with 17 samples.

How the data were processed

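RNA-seq and ATAC-seq were measured in sox10:GFP positive cranial neural crest cells sorted from pools of dissociated zebrafish embryos at 48 hours post fertilization. Per the labels' protocols, total RNA was extracted with Trizol and a column kit and libraries were made with a Pico input kit, and the ATAC libraries were made by tagmentation. The submitters' processing notes name TopHat2 2.1.1, Cufflinks, cutadapt, Bowtie2 2.4.4, Genrich, bedtools 2.30.0 and the build danRer11, without saying which step used which. Other parameters are not given in the sources used here.

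For RNA, the authors deposited 1 table per mutant, with a value per library, group means, a fold change, a p-value and a q-value for each listed gene. The unit of the library values is not named in the tables. They are taken here as FPKM made by the authors, because the submitters' processing notes name Cufflinks and the values are not whole. The authors' fold change is a signed ratio of the group means, and where a mean is 0 it holds the other mean, so no fold of such a gene is printed. The test behind the authors' p-value is not named, and a two-sided equal-variance test on log2(FPKM + 1) recomputed from the listed values gave the same p within 1% in all 1520 and 2990 rows. The numbers of genes tested, 11242 and 10623, were recovered from the relation of the deposited p-value and q-value. The prdm3 table holds genes with an unadjusted p below 0.05 and the prdm16 table genes with q below 0.05 (2988 gene IDs in 2990 rows), and the higher group mean was 0.996 or more and 0.995 or more, respectively. The prdm3 table uses wild type replicates 2 and 3 and all 3 mutants. Wild type replicates 1 and 2 are named in their labels for prdm3 and replicate 3 for prdm16, and all were taken as 1 wild type group, as their genotype is given. The word cleaned, which no source used here explains, stands in the labels of wild type replicate 1, prdm3 mutant replicate 2 and prdm16 mutant replicates 1 and 2. The prdm16 table uses all 3 wild type libraries and mutant replicates 1 and 2, and mutant replicate 3 is not analysed here. Columns were matched to samples by the names in the labels, and 0 columns of per-sample values were left unused. Wild type values were equal within 0.01 in 338 of the 339 genes shared by the tables. For ATAC, peaks were deposited per library, with a score, a signal (area under the peak) and a −log10 p for each peak by the authors' peak caller, and these served only to rank and filter peaks within a library.

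Gene symbols came from a table of gene IDs, which matched 1486 of 1520 and 2911 of 2988 IDs, and otherwise from the deposited tables. Counts of genes rest on the authors' own p and q, because genes that missed the authors' threshold are not held and a model over all genes cannot be fitted. The design fixed beforehand named limma for tables with values per library, so limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) was run on the listed rows as an alternative, with a prior estimated from rows already selected. Differences and standard errors are on the log2(FPKM + 1) scale, which understates the change of genes with low values. There were 24 gene lists and the ribosomal proteins, fixed before the data were examined along with the grouping, the tests and the rule for named genes. For each, the split of higher and lower listed members was set against that of the other listed genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment, where 3 or more members were listed. The lists cover Wnt pathway components and targets, cartilage, osteoblast, neural crest and arch, pigment, glia, neurons, otic vesicle, epidermis, blood, endothelium, muscle, lens and retina, cell cycle, matrix and adhesion, BMP and TGF-β, hedgehog, FGF, Notch, PRDM, histone H3 methylation, immediate early and heat shock, and p53. Genes adjusted over the list alone were counted with every unlisted member as a test that failed, so for the prdm16 table the count is a lower limit. Named genes are PRDM genes, the 8 with the largest difference in each direction among genes above 0 in both groups with a higher mean of 5 or more and a symbol of their own, and up to 4 members of each list with the smallest q. Others are marked as chosen after their values were seen. Some genes that meet the rule are not reported here. The overlap of the tables was set against independent lists and against 200 simulations of unchanged mutants that share the wild type libraries.

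ATAC peaks of the 4 libraries of a set were merged where they overlapped by 1 bp or more. Regions with a peak in exactly 1 pair of libraries were counted for each pair, again with equal numbers of strongest peaks per library, and the log2 peak number was compared by an exact permutation test. The 5 strongest regions per direction are those with the highest lower percentile rank of the −log10 p in the libraries that hold them. Read totals are not given with the peaks, so a missing peak can reflect depth, and the peaks covered 5.16 to 12.6 Mb per library. Pooled embryos stand behind each library and nothing states separate clutches, so p-values measure the spread between these samples only.

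On simulated data with 200 changed genes, limma recovered 79% of genes changed 2-fold and 96% of those changed 4-fold among 11242 genes in the prdm3 layout, with 8 false calls, and 13% and 64% among 10623 genes in the prdm16 layout, with 5 false calls. The simulated spread was drawn from wild type values of listed genes, which were selected for differing, and no loss of detection was simulated. These rates may be too high. They do not describe the reported counts, which rest on the authors' own p and q. Merging recovered 1888 of 1888 simulated regions. These lay well apart with peaks of equal width, so this checks the counting only and not peaks that lie close together. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Alternatives covered the threshold (q below 0.01), a log2 difference of 1 or more, genes at 0 left out, low values, the pseudocount (0.1 in place of 1), limma, a replicate block, a block on the number in the label, each replicate left out, a peak p of 0.001 or less, a 50% reciprocal overlap, assembled chromosomes, equal peak numbers and all 4 wild type ATAC libraries as controls. No count over other splits of the samples was made for gene calls, since each comparison has a group of fewer than 3. Motifs and genes near the regions were planned and are not analysed here, since no genome or annotation of danRer11 was used.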

Results

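Cranial neural crest cells, the migratory embryonic cells that form most of the facial skeleton, were collected from zebrafish embryos at 48 hours post fertilization by sorting cells that carry the sox10:GFP reporter. The series holds 17 samples. There are 9 RNA-seq libraries, 3 wild type, 3 prdm3 mutant and 3 prdm16 mutant. The other 8 are ATAC-seq libraries, which mark open chromatin. A prdm3 set and a prdm16 set each hold 2 wild type and 2 mutant libraries. The title of the series places Prdm3 and Prdm16, zinc finger proteins related to histone methyltransferases, in the control of Wnt/β-catenin activity and of cartilage cell differentiation. Each comparison asks what differed between mutant and wild type cells. Gene levels are FPKM values given as mean ± SD. In the prdm3 comparison n = 2 wild type and n = 3 mutant libraries, and in the prdm16 comparison n = 3 wild type and n = 2 mutant libraries. Read depth is unknown for both assays, because gene lengths and read totals are not part of the tables used here. Levels of mecom, the zebrafish name of prdm3, and of prdm16 itself are not analysed here, since neither gene is among those listed. The genotype labels were therefore not checked at the targeted genes. Each RNA label also opens with a number of its own, and the groups share only 1 such number in each comparison. Some labels hold the word cleaned, both prdm16 mutant libraries used here among them, and too few libraries share it for a comparison among these alone.

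In prdm3 mutant cells, 94.2% of all listed genes were higher than in wild type cells, among them 23 of 84 cell cycle, 14 of 68 neural crest and arch and 11 of 98 Wnt pathway genes. The de novo DNA methyltransferase gene dnmt3ba (ENSDARG00000052402) rose 1.78-fold, from 5.70 ± 0.0356 to 10.1 ± 0.0332 FPKM, with q = 0.0043 in the authors' deposited table. The ribosome biogenesis gene utp18 (ENSDARG00000102618) was listed at 1.54 and 1.51 in the wild type libraries and at 0 in all 3 mutant libraries (q = 0.00314 in the authors' deposited table). The small RNA RF00067 (ENSDARG00000113885) was listed at 902 and 1120 in the wild type libraries and at 0 in all 3 mutant libraries (q = 0.0131 in the authors' deposited table). These 3 genes, chosen after their values were seen, are all that passed q below 0.05. For utp18 and RF00067 this rests on values of 0, which can be failed estimates, as described for prdm16 mutants below. The authors' deposited table lists 1520 genes at an unadjusted p below 0.05, with 1432 higher and 88 lower in the mutant. By chance, 562 of the 11242 genes tested would be listed. The 1432 higher genes are a larger share of those tested than 11 of 98 Wnt pathway genes. They are a smaller share than in the cell cycle and neural crest and arch lists. List members not tested are counted in these shares.

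The largest listed differences toward the mutant were in slbp and lin28a. The gene slbp, whose product binds the stem-loop of histone mRNAs, was listed at 2.22 ± 0.148 in wild type and 10.4 ± 3.30 in mutant cells. The RNA-binding protein gene lin28a (ENSDARG00000016999) was listed at 11.5 ± 2.83 and 35.7 ± 11.7. On the log2(FPKM + 1) scale these differences were 1.79 ± 0.34 (SE) and 1.52 ± 0.37. The melanin synthesis gene dct was listed at 4.01 ± 2.12 and 12.4 ± 3.10 and mapk11 at 2.46 ± 0.836 and 8.15 ± 2.47. Values were 2.48 ± 0.967 and 8.29 ± 3.22 for mgrn1a and 1.41 ± 0.321 and 5.33 ± 1.23 for sncgb. The symbol pou2f2a stands on 2 gene IDs. They were listed at 4.09 ± 1.08 and 13.3 ± 3.30 for ENSDARG00000036816 and at 2.05 ± 0.0372 and 7.32 ± 1.87 for ENSDARG00000019658. In the other direction, sec61g, a subunit of the protein translocation channel, was listed at 22.1 ± 0.306 in wild type and 5.79 ± 0.267 in mutant cells. Its log2 difference was -1.77 ± 0.04 with q = 0.0749 in the authors' deposited table. The structured RNA RF00017 was listed at 15.5 ± 7.08 and 2.76 ± 0.918 and arhgap12b at 5.81 ± 0.432 and 1.43 ± 0.481. The cytokine signalling inhibitor socs1a was listed at 6.41 ± 2.87 and 1.76 ± 0.379 and snrnp35 at 7.16 ± 1.62 and 3.53 ± 0.376. Smaller values toward wild type were listed for epb41l3b (5.25 ± 0.349 and 2.58 ± 0.700), tex264a (5.005 ± 0.154 and 2.64 ± 0.561) and plxdc2 (10.6 ± 0.861 and 6.26 ± 1.31).

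Of the 84 cell cycle genes, 23 were listed higher and 1 (cks1b) lower in prdm3 mutants. Of these, 5 passed when adjusted over the list alone (mcm6, dnmt1, smc2, lig1 and uhrf1). The replicative helicase subunit mcm6 rose from 5.06 ± 0.350 to 11.04 ± 0.462 FPKM and the maintenance DNA methyltransferase dnmt1 from 8.70 ± 0.494 to 16.6 ± 1.01. The partner of dnmt1, uhrf1, rose from 10.8 ± 0.569 to 19.8 ± 1.56 and the condensin subunit smc2 from 0.871 ± 0.0201 to 1.73 ± 0.121. Each passed by that adjustment and not over all genes. Of the 68 cranial neural crest and arch mesenchyme genes, 14 were listed higher and 0 lower, with 0 adjusted over the list alone. Among them were the nuclear receptor gene nr2f2 (11.5 ± 0.657 and 23.0 ± 1.51) and the homeobox genes dlx4b (4.11 ± 0.196 and 8.36 ± 0.873) and meis1a (8.71 ± 0.0763 and 15.3 ± 1.61). Of the 98 Wnt pathway components, 11 were listed higher and 0 lower, with 0 adjusted over the list alone. They included the receptors ryk (10.3 ± 0.366 and 12.4 ± 0.141) and fzd3a (2.78 ± 0.453 and 4.53 ± 0.208). Also listed were the β-catenin cofactor bcl9 (23.5 ± 1.23 and 31.7 ± 2.05) and the inhibitor kremen1 (2.65 ± 0.0528 and 5.82 ± 1.16). The Wnt target list gave 2 higher genes of 26, with 0 adjusted over the list alone. These were ccnd1, which encodes cyclin D1 (32.2 ± 1.62 and 77.5 ± 11.9), and the feedback inhibitor nkd1 (3.75 ± 0.00803 and 6.78 ± 1.53). None of the 52 cartilage genes and none of the 34 osteoblast genes was listed.

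Of the 53 histone H3 methyltransferase and demethylase genes, 9 were listed higher in prdm3 mutants and 1, the H3K36 methyltransferase setd2 (9.96 ± 0.338 and 16.4 ± 0.578), passed when adjusted over the list alone. The others included jarid2b (14.0 ± 0.149 and 24.2 ± 1.83), kmt2a (8.90 ± 0.356 and 14.2 ± 0.917) and setdb1a (3.69 ± 0.0845 and 7.47 ± 0.944). In the PRDM family prdm2b (7.56 ± 0.408 and 12.1 ± 0.526), the member that passed when adjusted over the list alone, and prdm4 (2.24 ± 0.418 and 3.42 ± 0.390) were listed higher. The signalling lists had 0 genes adjusted over the list alone in each and none lower. Listed higher were 5 BMP and TGF-β genes (tgfbr1b at 4.72 ± 1.08 and 8.33 ± 1.04) and 3 Notch genes (lfng at 3.41 ± 0.246 and 8.81 ± 2.32). There were 2 higher hedgehog genes (gli2b at 7.86 ± 0.184 and 11.4 ± 1.299) and 2 higher FGF genes (dusp1 at 20.7 ± 3.64 and 40.8 ± 9.37). The matrix and adhesion list had 3 higher genes, among them ncanb (4.25 ± 0.948 and 10.2 ± 1.05). The ribosomal protein list had 4 higher (rpl3 at 417 ± 16.4 and 489 ± 11.6) and 1 lower (rps13 at 38.6 ± 2.51 and 32.4 ± 1.39). Both lists had 0 adjusted over the list alone. The p53 list had 1 higher gene (sesn1, 4.31 ± 0.485 and 7.63 ± 0.794). The immediate early and heat shock list had 1 higher (nr4a1, 0.98 ± 0.221 and 2.13 ± 0.391) and 1 lower (hspb9, 1.53 ± 0.432 and 0.157 ± 0.154), and in both lists 0 were adjusted over the list alone.

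Markers of other cells that the sort could hold were listed on both sides, with 0 adjusted over the list alone in each. The pigment genes dct and tyrp1b (6.67 ± 3.74 and 17.7 ± 1.61) and the glial gene sox2 (10.1 ± 1.60 and 18.2 ± 2.78) were listed higher in prdm3 mutants. So were the otic gene oc90 (0.347 ± 0.111 and 1.13 ± 0.272) and the epidermal gene krt91 (1.98 ± 0.603 and 5.62 ± 0.911). Of the neuronal genes 5 were listed higher, such as inab (3.75 ± 1.19 and 9.71 ± 1.44), and 1 lower. The neuronal gene sncb was listed at 1.78 and 2.36 in wild type and at 0, 0.644 and 0 in mutant libraries. The muscle gene tnnt3a was listed at 1.47 and 1.27 and at 0, 0 and 0.591. The lens crystallin genes crygm2d9 (1.43 and 0.814) and cryba1b (2.75 and 2.42) were listed at 0, 0 and 0 and at 0.705, 0 and 0.221 in the mutant libraries. No blood or endothelial marker was listed. In Fisher's exact test of the split between higher and lower genes, 0 of the 9 lists with at least 3 listed members differed at adjusted p below 0.05. At an unadjusted p below 0.05, 0 did. With 94.2% of listed genes higher, a list with every member higher could reach p = 0.394 by this exact test at the lowest, so it could only pick out lists with many lower members. The authors' deposited table leaves out genes that missed its threshold, so list members that did not differ were not counted and an enrichment over all genes tested was not computed.

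**Figure D1:**
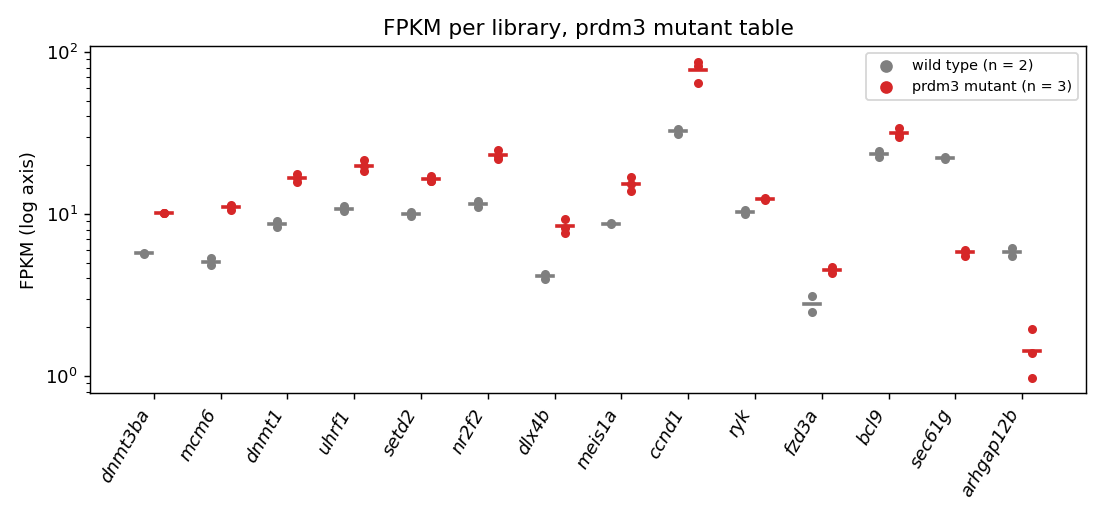
FPKM per library on a log axis for 14 genes of the prdm3 comparison, with gray points for the wild type libraries (n = 2), red points for the prdm3 mutant libraries (n = 3) and bars at the means. The mutant points of dnmt3ba, mcm6 and nr2f2 lie above the wild type points, and those of sec61g and arhgap12b lie below them.

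In prdm16 mutant cells most listed genes were lower than in wild type cells. Many were listed at 0 in both mutant libraries, among them Wnt pathway, skeletal and neural crest genes. Lower were 19 of 98 Wnt pathway, 9 of 52 cartilage, 7 of 34 osteoblast and 11 of 68 neural crest and arch genes. Each is a smaller share than the 2912 lower rows among 10623 genes tested, though list members not tested are counted. The authors' deposited table lists 2990 rows at q below 0.05 among 10623 genes tested, with 78 higher and 2912 lower in the mutant. Of the lower ones, 2540 were listed at 0 in both mutant libraries. Genes used by every cell were among these, such as the proteasome subunit psma4 (34.7, 20.25 and 27.2 in the wild type libraries) and the respiratory complex I subunit ndufs5 (27.4, 25.7 and 23.4). Another was the mitochondrial gene mt-atp8 (1014, 863 and 877). These genes were chosen after their values were seen. A value of 0 in these files can therefore be a failed estimate, and for genes at 0 the text gives each library's value only. Leaving out genes at 0 in every library of a group left 450 rows, 78 higher and 372 lower. Leaving out genes at 0 in any library, a choice made after seeing the data, left 128 rows, 77 higher and 51 lower. A gene at 0 in a mutant library is nearly always a lower one, so both filters take out lower genes by their nature and the remaining split does not measure direction.

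Among the genes that rose in prdm16 mutants, lin28a went from 13.8 ± 4.38 to 265 ± 93.9 FPKM, 19.2-fold. Its log2 difference was 4.16 ± 0.43 (SE) with q = 0.0173 in the authors' deposited table. The tubulin carboxypeptidase gene vash2 rose from 6.44 ± 1.32 to 151 ± 102 and the lysosomal transcription factor gene tfeb from 2.36 ± 1.16 to 49.1 ± 10.2. The septin gene sept5a rose from 5.61 ± 1.39 to 106 ± 70.9 and sh3glb2b from 1.62 ± 0.0379 to 47.9 ± 41.0. The rise was from 6.75 ± 0.929 to 89.7 ± 34.9 in nat16 and from 5.31 ± 2.51 to 53.6 ± 21.1 in r3hdm1. The small RNA RF00012 was at 0.00193, 0.00318 and 0.0196 in the wild type libraries and at 1278 and 2433 in the mutant libraries. Abundant genes chosen after their values were seen also rose. Among them were the translation factors eef1g (70.0 ± 1.91 to 205 ± 27.8) and eif5a (105 ± 12.1 to 312 ± 103). So did eef1a1l1 (1159 ± 65.7 to 1605 ± 19.0) and the mitochondrial gene mt-nd4 (163 ± 7.14 to 372 ± 91.6). FPKM is relative to the rest of a library. In libraries with 2540 listed rows at 0, these rises need not be rises per cell, which was not tested. Of the genes above 0 in both mutant libraries, the chromatin protein gene hmgb2b fell from 213 ± 40.4 to 5.61 ± 2.44. Its log2 difference was -5.06 ± 0.35 with q = 0.0107 in the authors' deposited table. The histone gene hist1h2a4 fell from 94.0 ± 18.8 to 1.38 ± 1.13 and RF01848 from 685 ± 543 to 0.427 ± 0.207. Other lower genes were above 0 in 1 mutant library only. The ribosomal protein gene rpl37 was listed at 97.1, 140 and 174 in wild type and at 0 and 1.92 in mutant libraries. The replication gene pclaf was listed at 72.2, 79.2 and 83.1 and at 4.03 and 0, and tuba1c at 47.2, 22.4 and 46.4 and at 0 and 0.405. The matrix protein gene sparc was listed at 27.4, 54.2 and 34.1 and at 0.487 and 0 and crebzf at 81.5, 54.3 and 62.3 and at 4.39 and 0.

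Of the 98 Wnt pathway components, 19 were lower and 0 higher in prdm16 mutants, 17 of them adjusted over the list alone. Both mutant libraries were at 0 for 13 of them. The receptor gene fzd1 was listed at 9.85, 10.8 and 8.30 in the wild type libraries and the secreted antagonist sfrp1a at 6.54, 7.61 and 5.69. Both were at 0 in the mutant libraries. All 6 listed Wnt targets, 6 of them adjusted over the list alone, were at 0 in both mutant libraries. They include the transcription factor lef1 (6.91, 6.25 and 6.66 in wild type) and nkd1 (5.34, 3.74 and 3.75). Of the 52 cartilage genes, 9 were lower (5 adjusted over the list alone, 5 at 0 in both mutant libraries). Among these, nkx3.2 was at 3.99, 4.16 and 4.80 in wild type and at 0 in both mutant libraries. The gene sox5, a cartilage and pigment regulator, fell from 80.3 ± 7.35 to 49.9 ± 1.60. Of the 34 osteoblast genes, 7 were lower, 7 of them adjusted over the list alone. At 0 in both mutant libraries were 5, such as the bone master regulator runx2b (2.55, 4.22 and 2.56 in wild type). All 11 listed neural crest and arch genes, 11 of them adjusted over the list alone, were at 0 in both mutant libraries. Among them were the crest specifier foxd3 (3.24, 3.10 and 3.40 in wild type), id2a (34.1, 30.5 and 43.8) and msx1b (11.8, 7.13 and 7.91).

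The remaining lists had the same direction in prdm16 mutants, apart from 3 genes that rose. These were the cytokinesis gene anln (8.37 and 17.8), the metalloproteinase inhibitor gene timp2b (4.999 and 23.4) and the H3K36 methyltransferase gene nsd1a (9.66 ± 1.41 and 20.6 ± 3.59). The cell cycle list had 1 higher and 17 lower genes (16 adjusted over the list alone, 15 at 0 in both mutant libraries, such as plk4 at 5.22, 4.89 and 4.74 in wild type). The matrix and adhesion list had 1 higher and 25 lower genes (19 adjusted over the list alone, 18 at 0, such as lama2 at 2.45, 3.15 and 2.495 in wild type). There were 16 lower BMP and TGF-β genes (14 adjusted over the list alone, 14 at 0, such as smad4a at 7.84, 8.25 and 9.11). Lower too were 6 hedgehog genes (6 adjusted over the list alone, 5 at 0, such as scube3 at 3.202, 4.77 and 3.37) and 5 FGF genes (5 adjusted over the list alone, 5 at 0, such as etv5b at 11.4, 16.7 and 7.96). The Notch list had 2 lower genes (2 adjusted over the list alone, 2 at 0, such as her8a at 2.98, 2.41 and 2.02). The PRDM list had 3 lower genes (3 adjusted over the list alone, 3 at 0 in both mutant libraries, such as prdm8 at 6.65, 4.59 and 4.77 and prdm4 at 2.203, 2.53 and 1.94). The histone H3 list had 1 higher and 3 lower genes (0 adjusted over the list alone, 3 at 0, such as ezh2 at 6.85, 3.93 and 4.62). The immediate early and heat shock list had 5 lower genes (3 adjusted over the list alone, 4 at 0, such as klf9 at 6.03, 5.91 and 7.24). The p53 list had 6 (1 adjusted over the list alone, 5 at 0, such as baxa at 6.90, 6.85 and 6.97) and the ribosomal protein list 15 (12 adjusted over the list alone, 8 at 0).

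Markers of other cell types were lower together with these groups in prdm16 mutants. There were 9 lower neuronal genes (3 adjusted over the list alone, 8 at 0 in both mutant libraries, such as gap43 at 17.5, 12.01 and 12.9 in wild type). Lower too were 4 glial genes (2 adjusted over the list alone, 4 at 0, such as nkx2.2a at 6.95, 4.48 and 5.03) and 4 blood genes (2 adjusted over the list alone, 4 at 0, such as the globin gene hbbe1.1 at 24.0, 19.3 and 19.7). The endothelial list had 2 (1 adjusted over the list alone, 2 at 0, such as aplnrb at 8.51, 7.71 and 5.44). The last lists had 0 adjusted over the list alone in each. The muscle list had 2 at 0 (nexn at 2.00, 2.53 and 1.86) and the lens and retina list 2 at 0 (otx5 at 2.55, 1.72 and 3.40). The epidermis list had 2 at 0 (spint1a at 1.28, 1.22 and 0.93), the otic list 1 at 0 (s100s at 1.02, 1.65 and 2.13) and the pigment list 1 lower gene, sox5. In Fisher's exact test of the split between higher and lower genes, 0 of the 18 lists with at least 3 listed members differed at adjusted p below 0.05. At an unadjusted p below 0.05, 0 did. With so few higher genes, p is 1 for any of the lists with every member lower, 15 of the 18.

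**Figure D2:**
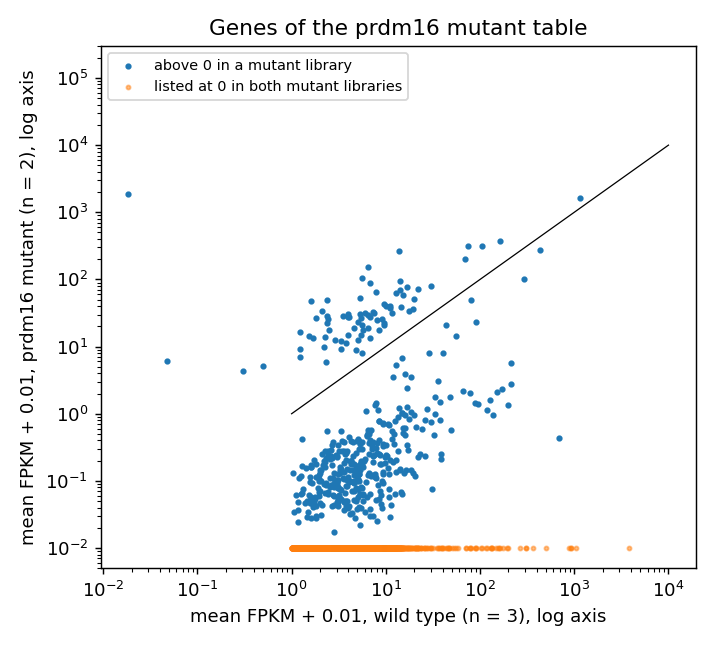
Mean FPKM of each row of the prdm16 comparison in wild type libraries (n = 3, horizontal log axis) and in prdm16 mutant libraries (n = 2, vertical log axis), with 0.01 added to each mean and a black line at equal values. The orange points along the lower edge are the 2540 rows listed at 0 in both mutant libraries, and the blue points above the line are the 78 higher rows.

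Set beside each other, the mutants shared 339 listed genes, and most of them stood on opposite sides. The prdm3 side rests on an unadjusted p, and the overlap was 0 at q below 0.01 in both and 33 at a log2 difference of 1 or more in both. There were 293 genes higher in prdm3 mutants and lower in prdm16 mutants, 16 higher in both, 30 lower in both and 0 lower in prdm3 mutants and higher in prdm16 mutants. Of the 293 genes on opposite sides, 244 were at 0 in both prdm16 mutant libraries, a value that can be a failed estimate. Wnt genes kremen1 and nkd1 and neural crest genes msx1b and hoxa2b are among these 244. The genes higher in both included lin28a (3.10-fold in prdm3 and 19.2-fold in prdm16 mutants), ddx61 (2.28 and 3.91) and anp32e (1.69 and 4.82). They also included the Notch pathway ubiquitin ligase gene mib1 (1.38 and 4.90), dnmt3ba (1.78 and 1.44) and eef1a1l1 (1.38 and 1.38). The prdm16 folds are relative to libraries with many genes at 0. Independent lists of these sizes would share 34.6 genes on the same side and 393 on opposite sides, against 46 and 293 observed. Simulated unchanged mutants measured against the same wild type libraries shared 17.9 on the same side and 1.05 on opposite sides (means of 200 simulations). Far fewer genes are listed in these simulations than in the data, so their counts are not comparable with 46 and 293. They show only that shared controls favour the same side. Splitting the wild type libraries would leave fewer than 2 in a part, so part of the overlap on the same side may come from the shared controls.

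In the prdm3 ATAC set, 2967 merged regions had a peak in both mutant libraries and in neither wild type library, and 685 had a peak in both wild type libraries only. Absence from all 4 wild type libraries of both sets left 1171 of the mutant-only regions. Splits that mix 1 mutant with 1 wild type library gave 643, 86, 74 and 10 regions, a mean of 203. The strongest mutant-only regions on assembled chromosomes lay on chromosome 25 (30441420 to 30442231, danRer11), 11 (8566958 to 8567690), 18 (13233570 to 13234096), 1 (605288 to 605520) and 24 (28382891 to 28383735). All 5 also had a peak in a wild type library of the prdm16 set. The strongest wild-type-only regions lay on chromosome 16 (666016 to 666932), 9 (35871 to 36879), 17 (46503266 to 46503449), 3 (1458854 to 1459457) and 24 (2750641 to 2751227). Mutant libraries held 18266 and 15115 peaks and wild type libraries 13658 and 8187. The log2 difference was 0.65 with p = 0.333 in a two-sided exact permutation test over 6 splits, the smallest p that 2 against 2 libraries allow. Without wild type replicate 1 or 2 the difference was 1.02 or 0.28. With the 8187 strongest peaks of each library, the mutant-only count was 638 and the wild-type-only count 487, against 279, 107, 168 and 62 for the mixed splits. The mutant-only count was 7915 without wild type replicate 1 and 3040 without wild type replicate 2. The lack of a wild type peak thus rested mostly on replicate 1. The mutant-only count was 3640 without mutant replicate 1 and 6361 without mutant replicate 2. Without wild type replicate 1 or 2 the wild-type-only count was 1732 or 1472. Counts rise in these settings, since a library left out need not hold or lack a peak. Genes near these regions were not analysed here, since no annotation of that build was used.

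In the prdm16 ATAC set, 50 merged regions had a peak in both mutant libraries only and 99 in both wild type libraries only. Absence from all 4 wild type libraries left 12 of the mutant-only regions. The mixed splits gave 3087 for the libraries numbered 1, 173 for those numbered 2, and 107 and 79. The strongest mutant-only regions lay on chromosome 17 (42949103 to 42949515, danRer11), 4 (67298026 to 67298505), 24 (12466334 to 12466729), 22 (10245172 to 10245723) and 10 (10894748 to 10895177), each with a peak in a wild type library of the prdm3 set too. Their lower percentile ranks were only 28.1 to 36.6, so each ranked below the middle of the peaks of a mutant library. The strongest wild-type-only regions lay on chromosome 4 (35240483 to 35240663), 10 (16036453 to 16036917), 15 (436642 to 437111), 24 (20927062 to 20927237) and 7 (61598866 to 61599046). Mutant libraries held 10682 and 6590 peaks and wild type libraries 14074 and 6777. The log2 difference was -0.22 with p = 0.667 in a two-sided exact permutation test. Without wild type replicate 1 or mutant replicate 2 the difference was 0.31 or 0.13. Leaving out wild type replicate 1 or 2 or mutant replicate 1 or 2 gave 687, 284, 223 or 679 mutant-only regions and 253, 4153, 988 or 151 wild-type-only regions. With the 6590 strongest peaks of each library, the mutant-only and wild-type-only counts were 126 and 151, against 604, 651, 145 and 130 for the mixed splits. The libraries thus grouped by replicate number more than by genotype.

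Between the wild type libraries of both sets, 623 regions separated the sets, 583 with peaks in the prdm3 set only and 40 in the prdm16 set only. A split of these 4 libraries by replicate number gave 4098 regions, 4000 in both libraries numbered 1 only and 98 in both numbered 2 only. The remaining split gave 131. Counted for 1 pair of libraries alone, the 2967 mutant-only regions of the prdm3 set stood above the 583 of the prdm3 set's wild type pair and below the 4000 of the pair numbered 1. With the 6777 strongest peaks of each library the 3 splits gave 322, 1414 (760 and 654) and 208 regions.

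**Figure D3:**
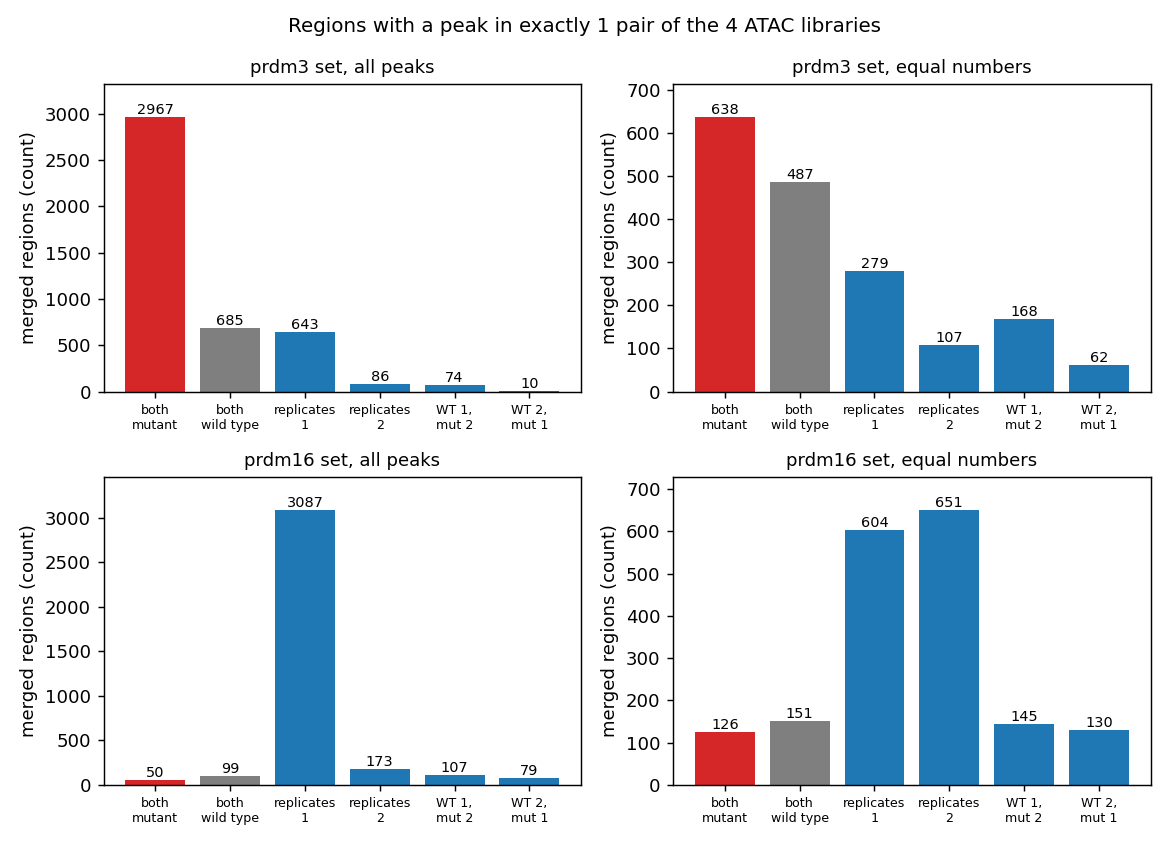
Number of merged regions with a peak in exactly 1 pair of the 4 ATAC-seq libraries of each set, for all peaks (left) and for equal numbers of strongest peaks (right), with red bars for both mutant, gray bars for both wild type and blue bars for mixed pairs. In the prdm3 set the red bar is the tallest (2967 and 638), and in the prdm16 set the tallest bars are mixed pairs with the same replicate number (3087 and 651).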

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

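The tests of scatter between mutant libraries and of general gene families, the bounds set on counts at equal peak numbers, and limma with the mutants set against each other, were chosen after the results they bear on were seen. At 334 of the 339 genes listed for both mutants, prdm3 and prdm16 mutant libraries differed by limma at adjusted p below 0.05, and prdm3 mutants were above prdm16 mutants at 320 of them. These genes were selected for differing from wild type, and 244 of the 293 on opposite sides are at 0 in both prdm16 mutant libraries. The difference between the mutants therefore rests largely on the values of 0 weighed next.

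The first pattern is the 2540 rows at 0 in both prdm16 mutant libraries, 87.2% of the lower ones, whose wild type values had a median of 2.99 FPKM and were 10 or more in 214 and 100 or more in 25. Absence of all these transcripts from the mutant cells is argued against by general gene families, in which 37 of 46 listed genes were at 0. These were 15 of 16 proteasome, 10 of 10 complex I, 8 of 15 ribosomal protein, 3 of 3 RNA polymerase II and 1 of 2 translation initiation factor 3 genes. Of the 6 families examined, the chaperonin subunits had 0 listed genes and do not bear on this. Loss of detection in libraries that sampled few transcripts may produce such values. The SD of the log2 difference was taken over 128 genes above 0 in all 5 libraries. It was 0.649 between the mutant libraries and at most 0.522 between wild type libraries. The ratio of 1.24 lies between the bounds set for and against that explanation and leaves it open. These genes were selected in the authors' deposited table by a test that favours a small spread within groups. A high ratio was thus less likely from the start, and the ratio does not weigh against loss of detection. Failed estimates in the authors' processing and a loss of prdm16 acting on part of these genes were not tested and stay open too, as does processing marked by the word cleaned in the labels of both mutant libraries. Wild type replicate 1 and prdm3 mutant replicate 2 carry the word too, but the listed genes were selected on differences that nearly all need values above 0 in these libraries, so such values do not bear on it.

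The second pattern is the excess of higher over lower genes in prdm3 mutants, 94.2% of 1520, with a median fold of 1.75 among the higher genes (10% to 90% range 1.38 to 2.83). An abundant transcript, FO704772.1, was listed at 114303 ± 8345 FPKM in wild type (n = 2) and 71892 ± 13793 in mutant libraries (n = 3). Its q was 0.364 in the authors' deposited table, so its fall is itself uncertain. A lower share of this transcript may raise all other genes by a common factor. The median of each list's higher members was set against random draws of higher listed genes of like wild type level. By these draws 0 of 9 list medians stood apart at adjusted p below 0.05 and 2 did at an unadjusted p below 0.05. The smallest adjusted p from the random draws was 0.0756. This does not separate a common factor from an effect on many genes. Low values in the 2 wild type libraries used may contribute. Wild type replicate 1, left out of that table, was below all 3 mutant libraries in 72.5% (224) of 309 higher genes that the other table also lists. This share lies between the bounds set for and against. Replicate 1 was above both other wild type libraries in 211 of these genes. A chance level of 25% would need replicate 1 and the mutants to be interchangeable. It does not apply to genes selected for mutant values above the other wild type libraries, and in the prdm16 comparison too. An effect of prdm3 loss on many genes stays open.

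The third pattern is the 2967 regions with a peak in both prdm3 mutant libraries only. With equal peak numbers the count fell to 638, while the wild-type-only count went from 685 to 487. More peaks in the mutant libraries thus stays open as a cause of much of the 2967. At equal numbers, 638 was 2.29 times the largest mixed split. Equal peak numbers do not make depth or quality of the libraries equal, so this does not exclude unequal libraries as a cause. Wild type pairs with the same replicate number, which have no difference of genotype, held 760 and 654 regions of their own at 6777 peaks per library. A count of this size can therefore arise without a difference of genotype. Regions open in wild type cells but without a called peak in the 2 wild type libraries of the set are a candidate explanation for many, since 60.5% (1796) had a peak in a wild type library of the prdm16 set, 1791 of them in replicate 1 and 29 in replicate 2. Library quality that differs between replicates stays open, and so does an effect of prdm3 loss on the other regions.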

How the results depend on the processing

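Of the alternatives, q below 0.05 in prdm3 mutants, genes at 0 in any library left out, and limma with all libraries, with another pseudocount, with the label number as a block and on the shared genes were chosen after seeing the data. Of 95 values, 65 kept their direction and their side of the threshold or moved little, 10 fell below the threshold used or to fewer genes, 18 moved and 2 changed direction. The 1520 prdm3 genes became 2 at q below 0.01, 3 at q below 0.05, 186 at a log2 difference of 1 or more and, among the 339 shared genes alone, 328 by limma with the same libraries and 260 (236 higher, 24 lower) with wild type replicate 1 added. The 2990 prdm16 rows became 631 at q below 0.01 and 450 without genes at 0 in a whole group, 128 (77 higher, 51 lower) without genes at 0 in any library, and the overlap of 339 became 0 at q below 0.01 and 33 at a log2 difference of 1 or more. Fewer genes pass or enter in these settings, apart from the step from 328 to 260, which came with replicate 1. Leaving out each replicate gave 1276 to 1450 prdm3 and 2975 to 2990 prdm16 calls by limma, against 1471 and 2988 with all libraries. Only listed genes could be called, so this says little about stability. The tests of list direction gave 0 in each setting run, which says little about stability, since a list on the side of most genes could not pass in the tables as listed. For prdm3 they were not run at q below 0.01 or at a log2 difference of 1 or more, since no list then keeps 3 members. The log2 difference in peak number ranged over replicates left out from 0.28 to 1.02 in the prdm3 set and from -0.75 to 0.31 in the prdm16 set, where it turned positive without wild type replicate 1 (0.31) and without mutant replicate 2 (0.13). Equal peak numbers gave 638 prdm3 and 126 prdm16 mutant-only regions, 151 prdm16 wild-type-only regions and 322 between wild type sets, and absence from all 4 wild type libraries left 1171 and 12 mutant-only regions. With a replicate left out, mutant-only regions numbered 3040 to 7915 and 223 to 687, and wild-type-only regions 801 to 1732 and 151 to 4153, since fewer libraries then need to hold or lack a peak. Apart from this, the cause was not tested. Neither the replicate numbers nor the numbers that open the RNA labels pair the samples in a stated way. With the label number as a block, 1239 and 2930 calls by limma were found, which rest on the 1 number that both groups share. With the replicate block, 1415 prdm3 and 2987 prdm16 calls by limma were found, the peak differences were 0.65 and -0.22, each with an exact permutation p of 0.5, the smallest that 2 pairs allow, and the region counts (2967, 685, 50 and 99) are the same by construction. Genes near regions and motifs were not run. Unknown depth limits every count of peaks and every value of 0.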

Other observations

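The comparisons in this part use values chosen after the data were seen. Genes higher in both mutants beyond those described above included the actin-bundling gene fscn1a (1.34-fold in prdm3 and 2.65-fold in prdm16 mutants), the glia maturation factor gene gmfb (1.78 and 6.95), the ankyrin gene ank2b (1.498 and 6.60), the translation factor gene eif4g2a (1.48 and 3.41), phf3 (1.74 and 5.40), tmtc3 (1.40 and 2.49), tefa (1.29 and 2.70) and nsd1a (1.31 and 2.14). The small RNA RF00067 (ENSDARG00000111557) was listed at 1133, 3607 and 6719 in the wild type libraries and at 0 in all prdm3 and prdm16 mutant libraries listed, and FO704772.2, a neighbour of FO704772.1 by name, was at 684 ± 88.7 in wild type (n = 2) and 357 ± 45.8 in prdm3 mutant libraries (n = 3). Of the prdm16 rows, 321 were at 0 in only 1 of the mutant libraries, and 5 had a mutant mean above 0 and below 0.01.

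Across all 8 ATAC libraries merged together with all peaks, the share of regions in common (Jaccard index) was highest for prdm3 mutant replicate 2 and prdm16-set wild type replicate 1 (0.758), followed by both prdm3 mutants (0.734) and by replicate 2 of the prdm16-set wild type and mutant libraries (0.709). The replicates of one genotype shared less in the prdm3-set wild type (0.467), the prdm16-set wild type (0.409) and the prdm16 mutants (0.524). With equal peak numbers both prdm3 mutants came first (0.772), followed by prdm3 mutant replicate 2 (0.757) and replicate 1 (0.746), each with prdm16-set wild type replicate 1.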
